A study of Mus with 35 samples.

How the data were processed

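RNA was measured in 35 brain libraries from male C57BL/6J mice, in 12 groups formed by cohort, genotype and injected antisense oligonucleotide (ASO). Each group had 3 libraries, except the P209L group given the Hnrnph2 ASO at 3 weeks, which had 2. Per the labels, total RNA was extracted and made into stranded total-RNA libraries. The labels name whole brain in the description of the design and dissected cortex in the extraction protocol, so the tissue cannot be fixed from them. The titles carry animal-like names, but the labels do not say outright that each library came from a separate animal.

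The authors deposited 1 table of TPM (transcript abundance per library), a measure that divides reads by transcript length and scales every library to the same total. The authors' processing notes name Trim Galore, STAR 2.7.1a, GATK 4.0.4.0, RSEM and the mouse build mm10, without the annotation, the filters or the strand setting. The table held 55573 rows, all 35 columns belonged to a sample, and the values had 2 decimals. A total of 237 rows shared a symbol with another row, 120 of them beyond the first of their symbol, and these rows were kept apart. Of the symbols, 38416 were found in a RefSeq table of the same build, which gave the coordinates. TPM keeps no read total, so the depth of each library is unknown, counting error cannot be given and tools for counts were not used. No genome sequence was at hand, so GC content was not analysed here. Splicing was not analysed here, since the table holds 1 value per gene.

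Groups and ages were taken from the labels. The WT libraries at 3 weeks were assigned to the P209L or the R206W cohort by the library number series in their titles, since the labels give no cohort for them. Replicate numbers were shared between groups, although the labels do not say that a number marks a shared animal, litter or day. In 2 comparisons the deviations of all 3 same-numbered pairs correlated over 0.1 across genes (lowest 0.123 and 0.104). These were mutants with the Hnrnph2 ASO against WT with the control ASO, at 8 weeks and in the R206W cohort. The fit with the number as a block is therefore given beside their results, a choice made from the same values. The titles also hold stems of animal names, and in no cohort did a stem occur with both ASOs. The P209L cohorts had 4 to 6 stems for each ASO, while the R206W cohort had 2.

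Genes with a mean of at least 1 TPM over the libraries of a fit were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend, two-sided). Values within 1 cohort came from a fit of that cohort alone. Averages over the 3 cohorts, the age effect and the differences between cohorts came from a fit of all 35 libraries with 1 mean per group. The Benjamini-Hochberg adjustment was made within each contrast, and a gene was called at an adjusted p under 0.05. Every adjusted p in the text comes from limma unless another test is named. The standard error (SE) beside a gene's log2 fold change is limma's. An SE beside a list median was taken over the list's genes, which are not independent replicates, and not over libraries. Hnrnph2 and Hnrnph1 were also compared by two-sided exact permutation tests, in which 3 libraries against 3 cannot give a p under 0.1. Over the cohorts, labels were permuted within cohort, where the smallest possible p is 0.00025.

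A total of 47 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a contrast. A list needed at least 3 tested members. The lists reported by name are those with a result in the average contrasts or the age effect that bears on a named gene or cell type. The tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. Added later were the cerebellar covariate, leaving out libraries for the averages, the age effect and the differences between cohorts, and the alternatives for list tests and correlations. By that rule Hnrnph2, Hnrnph1, Hnrnph3, Hnrnpf and Grsf1 were followed in every contrast. Within a cohort, the 5 largest rises and the 5 largest falls were named among called genes whose groups did not overlap in TPM. For the averages, the 10 largest in each direction were named among called genes with the same sign in all 3 cohorts, and for age among called genes whose groups did not overlap. Where none passed, the 3 genes with the smallest p were taken and are given as not passing. For lists, up to 4 members with the smallest p were taken, and unnamed gene models were replaced by the next named gene. Some genes that the rule selects are not reported here.

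The tests were tried on simulated data in which 200 genes were changed. At a log2 change of 1, the share recovered was 95% for the P209L mutation effect at 8 weeks, 88% for the ASO effect in P209L mice at 3 weeks, 96% for the ASO effect in WT of the R206W cohort and 100% for the average mutation effect. At a log2 change of 0.5 the shares were 44%, 42%, 63% and 93%. Of the calls, 2.11%, 7.8%, 3.64% and 7.21% were false. Camera and fry each called 0 of 40 lists without a change in every one of these simulations. The simulated genes varied independently, so the simulations do not test lists whose genes vary together.

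The alternatives were no filter on low values, a pseudocount of 0.1 TPM, median-of-ratios rescaling, robust eBayes, a replicate block, an animal-name block in the R206W cohort, fits of only the compared groups, a joint fit of all cohorts, ratios to reference genes, leaving out 1 library or 1 cohort, and a cerebellar covariate. Their effects are given after the results. Up to 100 splits of the same libraries were counted for each comparison of groups of 3.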

Results

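Brain RNA of male mice carrying the P209L or the R206W substitution in Hnrnph2 was compared with that of wild-type (WT) littermates. Hnrnph2 lies on the X chromosome and encodes an RNA-binding protein of the hnRNP H/F family, and both substitutions lie in the part of the protein that directs it to the nucleus. Each mouse received a single injection of 30 µg of a control ASO or of an ASO directed at Hnrnph2 into the brain ventricles shortly after birth. A P209L cohort was collected at 8 weeks, another P209L cohort at 3 weeks and an R206W cohort at 3 weeks. Every group had n = 3 libraries, except P209L with the Hnrnph2 ASO at 3 weeks (n = 2). The read depth is unknown, since TPM keeps no totals. Between 16235 and 16649 genes reached 1 TPM in each library. The 50 most abundant genes held 23.1% to 33.8% of all TPM, and mitochondrially encoded genes held 9.28% to 15.4%.

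The first question was how far the ASO lowered its target and whether related genes moved with it. Hnrnph2 (mm10, X:134601179 to 134607060) fell in every cohort and genotype. In WT mice it went from 105 ± 14.8 TPM (SD, n = 3) with the control ASO to 17 ± 4.5 at 8 weeks, which is 83.8% lower. It went from 109 ± 6.66 to 18 ± 1.49 in WT of the P209L cohort at 3 weeks (83.5% lower) and from 103 ± 12.1 to 24.9 ± 1.69 in WT of the R206W cohort (75.9% lower). In P209L mice it went from 98.9 ± 4.78 to 8.57 ± 2.65 at 8 weeks (91.3% lower) and from 101 ± 2.92 to 13.9 ± 1.58 at 3 weeks (n = 2, 86.3% lower). In R206W mice it went from 102 ± 7.89 to 21.3 ± 2.32 (79.1% lower). Each of these 6 differences had an exact two-sided p of 0.1, the smallest that 3 libraries against 3, or 3 against 2, allow. Over the cohorts the log2 fold change was -2.37 in WT (SE 0.088) and -2.80 in mutants (SE 0.092), each with an exact permutation p of 0.00025, the smallest possible. The mutations themselves left Hnrnph2 RNA within the spread of the replicates (log2 fold change -0.06, exact permutation p 0.28).

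Hnrnph1 (11:50375257 to 50386528), the closest relative of Hnrnph2, was higher with the Hnrnph2 ASO. In WT it went from 320 ± 18.5 to 411 ± 23.1 TPM (SD, n = 3) at 8 weeks, from 247 ± 5.55 to 390 ± 22.8 in the P209L cohort at 3 weeks and from 342 ± 25.1 to 408 ± 23.6 in the R206W cohort. In P209L mice it went from 339 ± 21.6 to 418 ± 12.6 at 8 weeks and from 271 ± 6.74 to 330 ± 0.686 at 3 weeks (n = 2), and in R206W mice from 323 ± 16.1 to 391 ± 27.8. Over the cohorts Hnrnph1 rose by 0.43 on the log2 scale in WT (SE 0.037) and by 0.29 in mutants (SE 0.039), each with an exact permutation p of 0.00025, the smallest possible. Within single cohorts limma called Hnrnph1 only in WT of the P209L cohort at 3 weeks (0.66, SE 0.053, adjusted p 0.00128). This call ended with a fit of those groups alone (adjusted p 0.0603) and with ratios to reference genes (log2 fold change 0.55, adjusted p 0.166). For the mutations the average change of Hnrnph1 was 0.05 (exact permutation p 0.274), with signs that differed between cohorts: 18.7 TPM higher in P209L at 8 weeks (exact p 0.4), 24.4 higher in P209L at 3 weeks (exact p 0.1, the smallest possible) and 18.3 lower in R206W (exact p 0.4). Hnrnph3 (10:63014664 to 63023980), Hnrnpf (6:117900340 to 117925622) and Grsf1 (5:88659233 to 88676171) were called in no mutation or ASO contrast, with average changes between -0.07 (Hnrnph3, mutation) and 0.08 (Grsf1, ASO in WT).

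**Figure D1:**
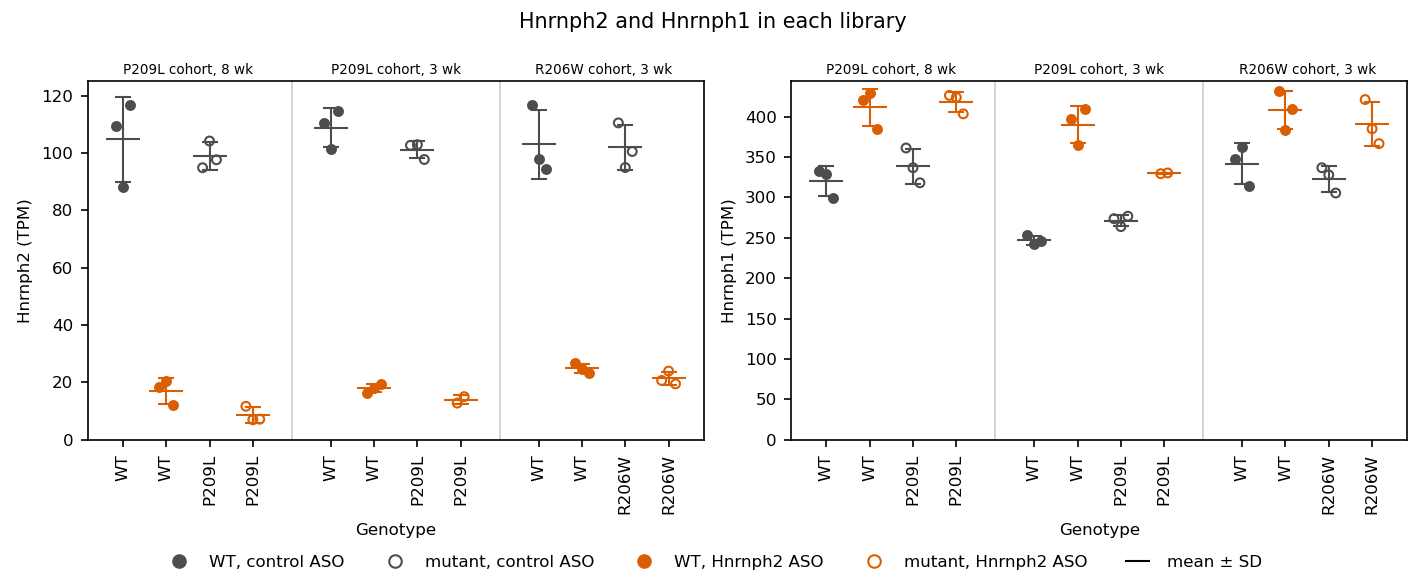
Hnrnph2 and Hnrnph1 in TPM for each library of the 12 groups, with grey for the control ASO, orange for the Hnrnph2 ASO, filled points for WT and open points for mutants; bars give the mean and SD. Hnrnph2 was lower and Hnrnph1 was higher in every library with the Hnrnph2 ASO than in each control library of the same cohort and genotype.

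The next comparison asked which genes differed in P209L mice at 8 weeks, both genotypes having received the control ASO. Ppp1r9b (11:94991212 to 95006898), which encodes the spine scaffold spinophilin, went from 332 ± 58.2 TPM in WT to 760 ± 5.61 in P209L (SD, n = 3; log2 fold change 1.21, adjusted p 0.00188). Ddn (15:98803782 to 98807925), which encodes the dendritic protein dendrin, went from 364 ± 105 to 751 ± 46.7 (1.08, adjusted p 0.026). Ilrun (17:27751232 to 27820542), a regulator of inflammatory signalling, went from 134 ± 15.9 to 266 ± 6.39 (1.00, adjusted p 0.000821). Shank1 (7:44308916 to 44360094), a scaffold of the postsynaptic density, went from 118 ± 24.4 to 227 ± 19.1 (0.95, adjusted p 0.0196), and Ppfia3 (7:45339126 to 45367019), a presynaptic active-zone protein, rose by 0.75 (SE 0.12, adjusted p 0.0335). limma called 28 genes, 27 higher and 1 lower. The lower gene was the unnamed model Gm20305 (-2.45), which fell alike with the ASO in WT against the same WT controls. The count was 84 without WT control replicate 3, and 6 or 8 without WT control replicate 1 or 2. It was 7, 5 and 5 without P209L control replicates 1, 2 and 3. The calls of Ddn, Shank1 and Ppfia3 ended without any of these libraries except WT control replicate 3 (adjusted p 0.101 to 0.144 for Ddn, 0.0504 to 0.116 for Shank1 and 0.0908 to 0.18 for Ppfia3).

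At 3 weeks the same question was asked of the younger P209L cohort. Ddn went from 299 ± 5.46 TPM in WT to 758 ± 24 in P209L (SD, n = 3; log2 fold change 1.34, adjusted p 5.73e-05). Ppp1r9b went from 330 ± 2.7 to 752 ± 2.8 (1.19, adjusted p 1.69e-05), Shank1 from 124 ± 5.44 to 226 ± 8.49 (0.86, adjusted p 0.000183) and Ilrun from 123 ± 0.748 to 214 ± 5.13 (0.80, adjusted p 5.15e-05). Tnpo2 (8:85036873 to 85057585), which encodes a receptor for nuclear import, rose by 0.85 (SE 0.070, adjusted p 0.000511). All 22 called genes were higher. The count was 13, 14 and 14 without WT control replicates 1, 2 and 3, and 11, 13 and 12 without P209L control replicates 1, 2 and 3.

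R206W mice at 3 weeks were compared with their own WT littermates to ask whether another substitution in the same signal changed the same genes. Ddn went from 204 ± 14.9 TPM in WT to 566 ± 89.3 in R206W (SD, n = 3; log2 fold change 1.46, adjusted p 0.000103), and Ppp1r9b from 264 ± 8.18 to 538 ± 77.4 (1.01, adjusted p 0.000235). Shank1 went from 104 ± 7.13 to 161 ± 7.33 (0.64, adjusted p 0.00758). Tnpo2 rose by 0.67 (SE 0.049, adjusted p 0.000137) and Adra1b (11:43774605 to 43901250), an adrenergic receptor, by 0.94 (SE 0.13, adjusted p 0.0155). Cbln3, a gene of cerebellar granule cells, fell from 125 ± 22.1 to 72.3 ± 5.31 TPM (-0.76, adjusted p 0.0395). The calls of Adra1b and Cbln3 ended with the animal-name stem as a block. Of 22 called genes, 21 were higher and 1 was lower. A fit with the replicate number as a block called 210, 102 higher and 108 lower. The count of 22 was 12, 10 and 13 without WT control replicate 1, WT control replicate 2 and R206W control replicate 1. Without any of these libraries the call of Adra1b ended (adjusted p 0.071 to 0.0885), and that of Cbln3 ended without any library except WT control replicate 3 (adjusted p 0.0799 to 0.179).

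A set of 9 genes was called higher in the mutants of all 3 cohorts: Ppp1r9b, Ddn, Shank1, Ilrun, Tnpo2, Brsk1, Fbxl19, Foxo4 and the unnamed model Gm31166. Brsk1 encodes a kinase of neuronal polarity and the presynapse, Fbxl19 a protein that binds unmethylated CpG islands and Foxo4 a transcription factor. Brsk1 rose by 0.59, 0.56 and 0.46 on the log2 scale in the P209L cohort at 8 weeks, the P209L cohort at 3 weeks and the R206W cohort. Foxo4 rose by 0.55, 0.58 and 0.50, and Fbxl19 by 0.51, 0.64 and 0.46. A further 9 genes were called in only 2 of the cohorts, among them Adra1b, Dzip1, Phactr3 and Ppfia3. Pairs of cohorts shared 11 to 13 called higher genes, where 0.029 to 0.037 would be shared if calls were independent. Across 15969 genes, which are not independent replicates, the mutation effects of different cohorts correlated with a mean r of 0.248. These pairs of cohorts share no library. The 9 genes kept a positive log2 fold change in each cohort with every filter, scaling, block and fit tried and with any 1 library left out (ratios to reference genes were not counted), but their calls depended on the fit. With only the compared groups in the fit, limma called 0 of the 9 in P209L at 8 weeks (9 at an unadjusted p under 0.05), 9 in P209L at 3 weeks and 2 in R206W. Called in all 3 cohorts were 5 with rescaled values and 3 with no filter on low values. At 8 weeks 3 were called without WT control replicate 1, P209L control replicate 2 or P209L control replicate 3, and 4 without WT control replicate 2 or P209L control replicate 1. At 3 weeks the call of Foxo4 ended without any 1 of the P209L cohort's control libraries. In the R206W cohort 5 were called without WT control replicate 1 or 3, 6 without WT control replicate 2 and 7 without R206W control replicate 1.

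**Figure D2:**
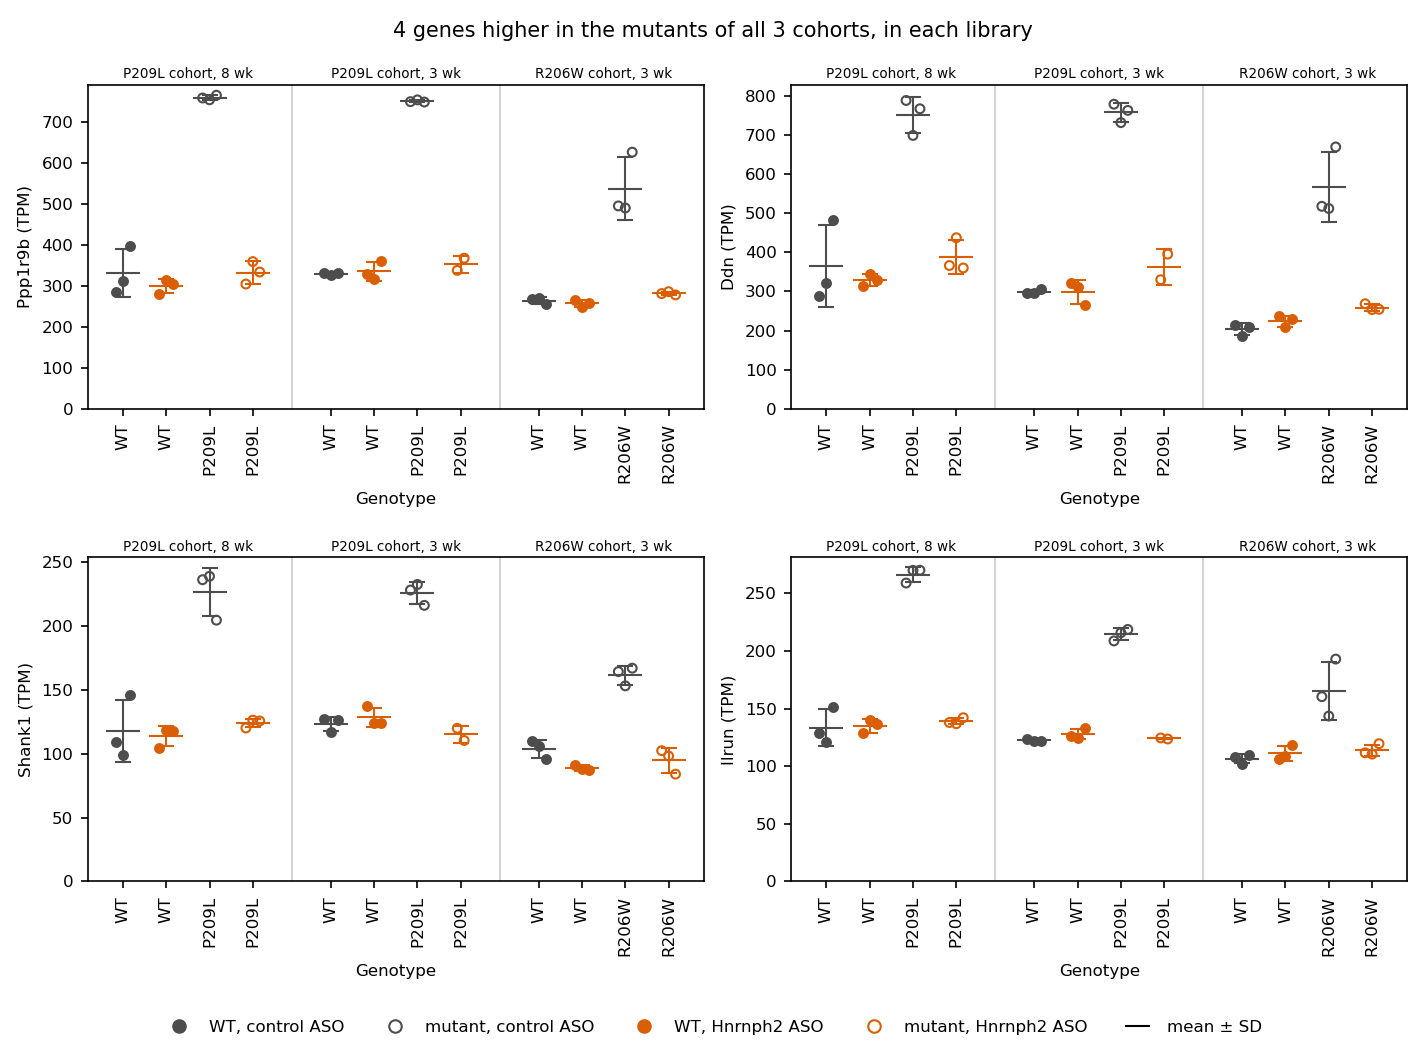
Ppp1r9b, Ddn, Shank1 and Ilrun in TPM for each library, with grey for the control ASO, orange for the Hnrnph2 ASO, filled points for WT and open points for mutants; bars give the mean and SD. Mutants with the control ASO stood apart from the other groups of their cohort, for Ppp1r9b at means of 760, 752 and 538 TPM.

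Averaging the mutation effect over the 3 cohorts asked which smaller differences the substitutions share (9 mutant and 9 WT libraries). Besides Ddn (log2 fold change 1.29, SE 0.073, adjusted p 1.95e-12), Ppp1r9b (1.14, SE 0.051, adjusted p 1.7e-14), Shank1 (0.82, SE 0.055, adjusted p 4.91e-11), Adra1b (0.81, SE 0.081, adjusted p 1.56e-07), Ilrun (0.81, SE 0.043, adjusted p 7.94e-13) and Tnpo2 (0.75, SE 0.046, adjusted p 6.97e-12), the largest rises were in Dzip1, Phactr3, Ppfia3 and Ppm1a. Dzip1, a protein of the ciliary base, rose by 0.63. Phactr3, a regulator of a phosphatase and of actin, rose by 0.62. Ppfia3 rose by 0.60 and the phosphatase gene Ppm1a by 0.60 (adjusted p 4.27e-08 and 2.31e-06). Among the genes that fell, Gabra6, a GABA receptor subunit of cerebellar granule cells, changed by -0.58 (SE 0.11) and Cbln3 by -0.55 (SE 0.090). Eomes, a transcription factor of unipolar brush cells, changed by -0.67 and the immediate early gene Fosb by -0.63. The lens-filament gene Bfsp2 changed by -0.66, the lymphocyte receptors Crtam and Cd6 by -0.57 and -0.50, and Bcl2l15, Tnnc1 and Cox8b by -0.51, -0.51 and -0.50. limma called 708 genes, 422 higher and 286 lower, against 349 higher and 154 lower with the cerebellar markers as a covariate. Without WT control replicate 3 of the 8-week cohort it called 1164, 720 higher and 444 lower. The lower count was 184 without WT control replicate 1 of that cohort and 181 without P209L control replicate 1 at 3 weeks. The calls of Eomes and Fosb ended without any 1 of 13 and of 10 of the 18 libraries (adjusted p up to 0.0976 and 0.0829).

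Some genes of myelin, of vessels and of neuronal activity were lower in the average over the mutants, although none of these lists passed with the estimated correlation. Of 21 tested genes of myelinating oligodendrocytes, 5 were called, all lower, and 10 adjusted over the list alone. Their median was -0.17 and the adjusted p with the estimated correlation was 0.459. The tight-junction gene Cldn11 changed by -0.27 (SE 0.054), Cnp by -0.24, Opalin by -0.28 and Mog by -0.23. Of 30 immediate early genes, 3 were called lower, Apold1 (-0.47), Dusp5 (-0.44) and Fosb, and 10 were lower adjusted over the list alone (median -0.26, adjusted p with the estimated correlation 0.459). Of 14 genes of pericytes and smooth muscle, Vtn (-0.26) and Tagln (-0.29) were called, and 6 were lower adjusted over the list alone (median -0.16, adjusted p with the estimated correlation 0.459). Of 17 genes of vascular leptomeningeal cells, Igf2 (-0.38) and Slc22a6 (-0.34) were called, and 6 were lower adjusted over the list alone (median -0.23, adjusted p with the estimated correlation 0.556). By cohort, in the order P209L at 8 weeks, P209L at 3 weeks and R206W, the list medians were -0.202, -0.229 and -0.134 for myelin, -0.0111, -0.274 and -0.208 for pericytes and smooth muscle and -0.158, -0.16 and -0.335 for leptomeningeal cells. For immediate early genes they were -0.555, -0.303 and 0.0912, with 20 of 30 genes above 0 in R206W. The difference between P209L and R206W at 3 weeks did not pass for this list with the estimated correlation (adjusted p 0.581). Lists of blood cells were lower as well, with medians of -0.339 for 8 erythrocyte genes and -0.273 for 6 peripheral leukocyte genes. limma called 0 in either list (2 at an unadjusted p under 0.05 in each), and the adjusted p with the estimated correlation was 0.931 and 0.514. The average count was 3 for myelin without any 1 of 11 of the 18 libraries, and 1 for pericytes without any 1 of 10. Without WT control replicate 3 of the 8-week cohort, 9 immediate early genes, 7 myelin genes and 5 leptomeningeal genes were called. Without WT control replicate 1 of the 8-week cohort, 2 immediate early genes, 3 myelin genes and 1 pericyte gene were called. Without P209L control replicate 1 of the 3-week cohort limma called 0 of the leptomeningeal genes, with 6 at an unadjusted p under 0.05. It called 1 of them without WT control replicate 1 or 2 or P209L control replicate 2 or 3 at 8 weeks, WT control replicate 2 of the P209L cohort at 3 weeks, or WT control replicate 1 or R206W control replicate 1 of the R206W cohort.

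Of 18 cerebellar markers, 5 were called lower, with Cbln3, Gabra6 and Eomes among them, and Slc1a6, a glutamate transporter of Purkinje cells, was called higher (0.41, SE 0.078). Adjusted over the list alone, 9 were lower and 1 was higher (median -0.19, adjusted p with the estimated correlation 0.594), and 3 to 7 members were called with 1 library left out, 3 without any 1 of 10 of the 18 libraries, WT control replicate 1 of the 8-week cohort among them, and 7 without WT control replicate 3 of that cohort. Of 39 genes of the postsynaptic density, 4 were called higher and 7 were higher adjusted over the list alone. They were Shank1, the scaffold Dlg4 (0.18) and the kainate receptor subunits Grik4 (0.28) and Grik1 (0.17), but the list's median was 0.06 (adjusted p with the estimated correlation 0.955). Among 19 genes of GABA receptors and the inhibitory synapse, Gabra3 (0.32) and Gabra5 (0.23) were called higher, with 4 higher and 1 lower adjusted over the list alone (median 0.06, from 0.0272 without WT control replicate 2 to 0.115 without WT control replicate 3 of the 8-week cohort, adjusted p with the estimated correlation 0.963). That median was 0.0327 without WT control replicate 2 of the P209L cohort at 3 weeks, and 0.0836 and 0.035 without WT control replicate 1 and R206W control replicate 1 of the R206W cohort. Of 17 heat shock genes, Cryab (-0.39), Hsph1 (-0.22) and Stip1 (-0.13) were called lower, with 7 lower adjusted over the list alone (median -0.10, adjusted p with the estimated correlation 0.459). Of 27 other hnRNP genes, Taf15 (-0.26) and Hnrnpc (-0.15) were called lower, with 7 lower and 1 higher adjusted over the list alone (median -0.06, and -0.039 without WT control replicate 1 of the R206W cohort, adjusted p with the estimated correlation 0.733). Camera with the preset correlation passed 2 of 47 lists upward and 15 downward, and 0 passed with the estimated correlation, where the smallest adjusted p was 0.459.

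In WT mice the Hnrnph2 ASO asked what loss of the normal transcript changes by itself. At 8 weeks limma called 3 genes, all lower: Hnrnph2 (-2.58, SE 0.21, adjusted p 0.0015) and the unnamed models Gm14539 (-0.70) and Gm20305 (-2.45), named here after their values were seen. Gm20305 had the same value for the P209L mutation at 8 weeks, a contrast with the same WT controls. High values in those controls would give both falls, so neither can be credited to the mutation or the ASO. The count of 3 was 1 without WT control replicate 1, WT control replicate 2 or WT Hnrnph2 ASO replicate 2. At 3 weeks in the P209L cohort it called 2 genes, Hnrnph2 (-2.54, SE 0.081, adjusted p 2.09e-07) and Hnrnph1, with 7 and 4 without WT control replicates 2 and 3. There Rufy1 (-0.48, adjusted p 0.498), Crybb1 (0.40, adjusted p 0.498) and Snora41 (3.21, adjusted p 0.372) did not pass. In the R206W cohort it called Hnrnph2 (-2.0, SE 0.098, adjusted p 3.54e-06) and the unnamed model Gm26493 (3.07), again named after its value was seen. That count of 2 was 4 without WT control replicate 1 and 1 without WT control replicate 3 or WT Hnrnph2 ASO replicate 1.

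Averaged over the 3 cohorts, the ASO in WT changed a small set of genes besides Hnrnph2 and Hnrnph1. Rufy1 (11:50389286 to 50431274), an endosomal adaptor gene next to Hnrnph1, changed by -0.44 (SE 0.049, adjusted p 6.7e-06). Taf15, an RNA-binding protein gene, changed by -0.37 (SE 0.062, adjusted p 0.0044). Mpnd changed by -0.30 and Marcksl1, a regulator of actin in young neurons, by -0.24 (adjusted p 0.000153 and 0.00813). The falls in Brinp3, Tbc1d19, Lhpp, Pcp4 and Impdh1 ran from -0.33 to -0.21. Spink10 rose by 0.59 and the phosphatase gene Ptpn6 of immune cells by 0.33 (adjusted p 0.00512 and 0.00672). Aspdh and Hpn rose by 0.48 and 0.47, and Emc8, Fuca2, Rtl8c and Cbarp by 0.25, 0.23, 0.21 and 0.15. limma called 31 genes, 16 higher and 15 lower, against 35 genes, 13 higher and 22 lower, with rescaled values. The calls of Aspdh and Pcp4 ended without any 1 of 13 of the 18 libraries, those of Hpn and Tbc1d19 without 12, of Brinp3 without 11, of Emc8 without 9, of Lhpp without 6 and of Impdh1 without 4 (adjusted p up to 0.137). Their log2 fold changes then kept their sign, with Aspdh between 0.44 and 0.54 and Impdh1 between -0.23 and -0.17.

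No list passed with the estimated correlation for the ASO in WT, where the smallest adjusted p was 0.844. limma called 0 of 22 type I interferon genes, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.18, adjusted p with the estimated correlation 0.961). It called 0 of 20 reactive astrocyte genes (7 at an unadjusted p under 0.05, 2 higher adjusted over the list alone, median 0.31, adjusted p with the estimated correlation 0.961). WT Hnrnph2 ASO replicate 3 of the P209L cohort at 3 weeks carried much of that rise, with a mean of these genes of 4.04 on the log2 scale beside 2.742 and 2.618 in the other libraries of its group. Without it the median was 0.113. That library also had the lowest share of mitochondrially encoded genes (9.28%) and of the 50 most abundant genes (23.1%). limma called 0 of 19 activated microglia genes (10 at an unadjusted p under 0.05, 4 higher adjusted over the list alone, median 0.13, adjusted p with the estimated correlation 0.844). The medians of 8 erythrocyte genes were -0.137 at 8 weeks, 0.398 in the P209L cohort at 3 weeks and 0.885 in the R206W cohort. In each cohort limma called 0 of them, and blood in the tissue was not tested for this contrast. Of 27 genes of the integrated stress and unfolded protein response, 0 were called (11 at an unadjusted p under 0.05) and 8 were lower adjusted over the list alone (median -0.06, and -0.0329 without WT control replicate 1 at 8 weeks, adjusted p with the estimated correlation 0.844).

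In mutants the question was whether lowering Hnrnph2 moves the mutation's genes back toward WT. At 8 weeks the ASO took Ppp1r9b from 760 ± 5.61 to 333 ± 27.5 TPM in P209L mice (SD, n = 3; log2 fold change -1.19, adjusted p 0.00143), beside 332 ± 58.2 in WT with the control ASO. Ilrun went to 139 ± 2.76 (-0.93, adjusted p 0.000805) and Shank1 to 124 ± 3.37 (-0.86, adjusted p 0.0291). Rufy1 changed by -0.63 and Phactr3 by -0.60, while Bfsp2 rose by 1.17 and the interferon-induced gene Ifi27 by 0.54. limma called 15 genes, 2 higher and 13 lower, and the count was 8, 8 and 9 without P209L control replicate 2, P209L control replicate 3 and P209L Hnrnph2 ASO replicate 1. The call of Shank1 ended without any of the 6 libraries (adjusted p 0.0619 to 0.159), and that of Rufy1 ended without any but P209L Hnrnph2 ASO replicate 1 (adjusted p 0.118 to 0.169).

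In P209L mice at 3 weeks (n = 2 with the Hnrnph2 ASO), Ppp1r9b went from 752 ± 2.8 to 353 ± 21.1 TPM (log2 fold change -1.09, adjusted p 6.12e-05) and Ddn from 758 ± 24 to 363 ± 46.3 (-1.07, adjusted p 0.000953). Shank1 went to 115 ± 6.75 TPM (-0.97, adjusted p 0.000191), Tnpo2 changed by -0.87 and Dzip1 by -0.83. Crybb1, a crystallin gene also expressed by microglia, rose by 1.06 (adjusted p 0.000191). limma called 16 genes, 1 higher and 15 lower, and 47 without P209L Hnrnph2 ASO replicate 1. The call of Dzip1 ended without P209L control replicate 1 or 2 or P209L Hnrnph2 ASO replicate 2 (adjusted p 0.167 to 0.372). The series holds no further library of this group, so values beyond these were not analysed here.

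In R206W mice Ddn went from 566 ± 89.3 to 259 ± 8.36 TPM (SD, n = 3; log2 fold change -1.12, adjusted p 0.000453), Ppp1r9b from 538 ± 77.4 to 282 ± 3.99 (-0.92, adjusted p 0.000453) and Shank1 from 161 ± 7.33 to 94.9 ± 9.63 (-0.77, adjusted p 0.00115). Tnpo2 changed by -0.70 (adjusted p 8.4e-05) and Rac3, a small GTPase of neurons, by -0.58. All 16 called genes were lower. In this cohort the control ASO went to animals of 2 name stems and the Hnrnph2 ASO to animals of 2 others. Within a genotype the ASO effect therefore cannot be separated from the stem. WT and R206W animals with the Hnrnph2 ASO carried the same stems. The 9 genes called higher in all 3 cohorts changed by -1.12 (Ddn) to -0.34 (Brsk1) in R206W. In WT they changed by -0.22 (Shank1) to 0.18 (Gm31166). This argues against a stem difference shared by both genotypes as the whole cause for these genes, but 2 points weaken it. Among the controls, R206W control replicate 3 carried a stem that no WT control had. The 9 genes were also chosen partly as higher in these R206W controls than in these WT controls, which favours a fall in mutants alone. The count of called genes was 43 without R206W control replicate 3, and 10, 9 and 10 without R206W Hnrnph2 ASO replicates 1, 2 and 3. The call of Rac3 ended without R206W control replicate 1 or any of the 3 Hnrnph2 ASO replicates (adjusted p 0.0968 to 0.171).

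**Figure D3:**
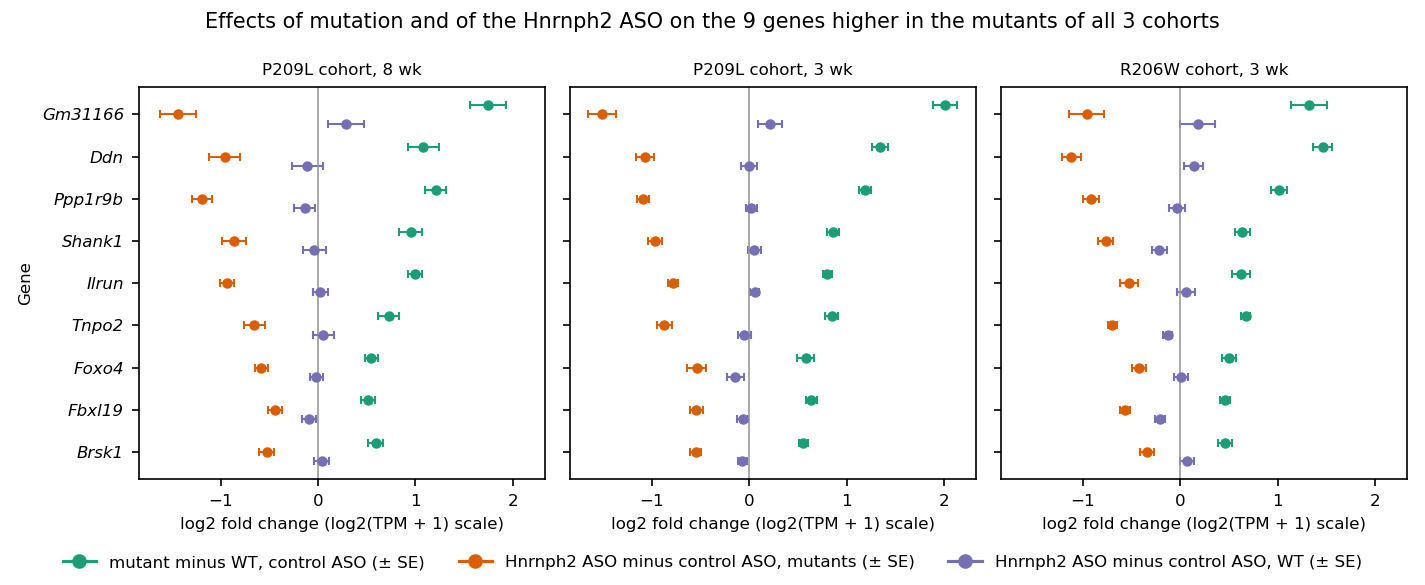
Log2 fold changes of the 9 genes called higher in mutants of all 3 cohorts, for the mutation, for the ASO in mutants and for the ASO in WT, with bars for the SE. The ASO effects in mutants ran opposite to the mutation effects, as for Ppp1r9b at -1.19, -1.09 and -0.92. Of the 9 genes, only Ppp1r9b and Shank1 were called lower with the ASO in mutants of all 3 cohorts. None of the 9 was called for the ASO in WT.

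The ASO effect in mutants was then averaged over the 3 cohorts (9 mutant libraries with the control ASO, 8 with the Hnrnph2 ASO). Of the 422 genes called higher for the mutation, 139 were called lower with the ASO and 3 higher, and of the 286 called lower for the mutation, 35 were called higher and 0 lower. Both effects use the mutant controls, which favours opposite signs. Ppp1r9b changed by -1.07 (SE 0.053, adjusted p 1.1e-13), Ddn by -1.05 (SE 0.076, adjusted p 2.96e-10), Shank1 by -0.86 (SE 0.057, adjusted p 3.91e-11), Ilrun by -0.75 (SE 0.045, adjusted p 8.77e-12) and Tnpo2 by -0.74 (SE 0.048, adjusted p 3.07e-11). Dzip1 changed by -0.67, Adra1b by -0.61 and Egfem1 by -0.57. Rufy1, which the ASO also lowered in WT, changed by -0.58. Oasl2, an antiviral gene of the interferon response, rose by 1.02 (SE 0.22, adjusted p 0.00869). The rises of the interferon-induced genes Isg15, Ifit3, Irf7, Ifit1, Rtp4, Usp18, Bst2 and Ifit3b ran from 0.97 for Isg15 to 0.69 for Ifit3b, and Lyz2, a lysozyme of microglia and macrophages, rose by 0.69 (adjusted p 0.0134). Each of these 10 calls ended without Hnrnph2 ASO replicate 2 of the P209L cohort at 3 weeks, with adjusted p of 0.0904 for Oasl2, 0.276 for Isg15, 0.157 for Irf7 and 0.0557 for Lyz2. The call of Ifit3 also ended without P209L control replicate 2 of that cohort (adjusted p 0.0522), and those of Isg15, Usp18, Bst2, Ifit3b and Ifit1 ended without any 1 of 11, 11, 10, 13 and 6 of the 17 libraries. limma called 414 genes, 197 higher and 217 lower. Without Hnrnph2 ASO replicate 2 of the P209L cohort at 3 weeks 73 were higher and 136 lower. The higher count was also 128 without P209L control replicate 1 at 8 weeks and 124 without P209L control replicate 2 at 3 weeks. It was 122 without R206W control replicate 1, and 124 and 128 without R206W Hnrnph2 ASO replicates 1 and 2.

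The interferon genes were higher by unequal amounts in single libraries. Isg15 was at 5.18 ± 0.889 TPM in P209L mice with the control ASO at 3 weeks and at 25.8 ± 27 with the Hnrnph2 ASO (n = 2). In R206W mice it was at 11.6 ± 8.62 and 14 ± 2.82, and in P209L mice at 8 weeks at 3.41 ± 0.788 and 6.84 ± 0.912. The mean of the interferon genes on the log2 scale was 3.764 in R206W control replicate 3, beside 2.649 and 2.977 in replicates 1 and 2. R206W libraries with the Hnrnph2 ASO lay between 3.373 and 3.678. Of 22 type I interferon genes, 13 were called higher and 19 adjusted over the list alone (median 0.55, adjusted p with the estimated correlation 0.361). Without Hnrnph2 ASO replicate 2 of the P209L cohort at 3 weeks limma called 0 of them, with 14 at an unadjusted p under 0.05 and a median of 0.34. Without replicate 1 of the same group it called 19, and without any other of these libraries 5 to 17. fry, which asks whether a list's genes move one way and does not compare them with other genes, gave an adjusted p of 0.0121.

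**Figure D4:**
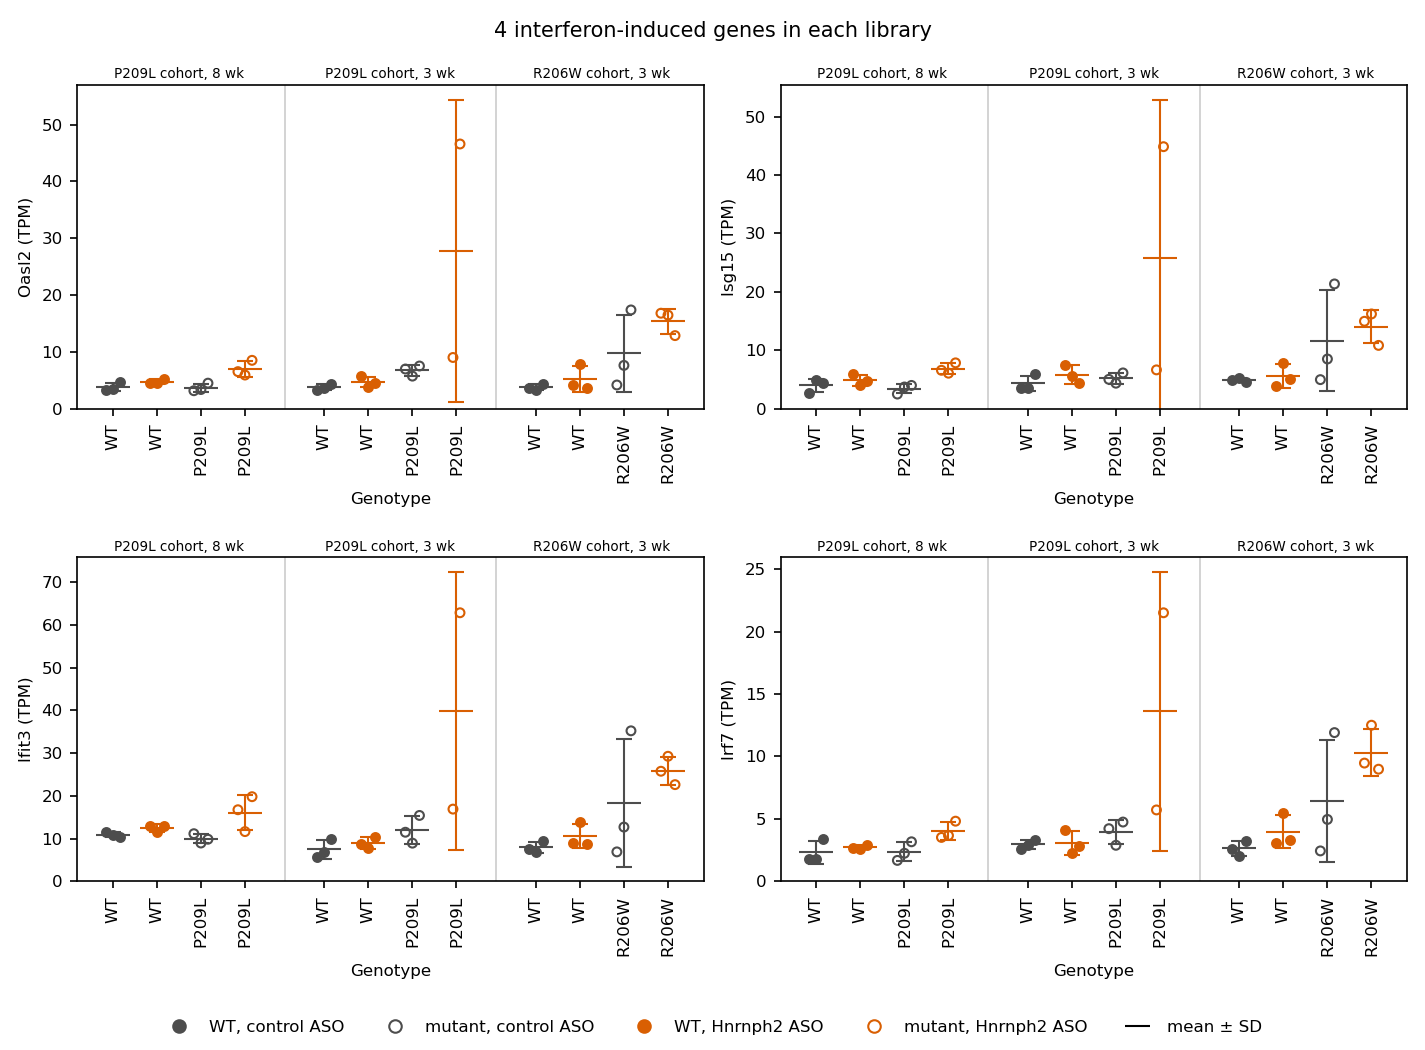
Oasl2, Isg15, Ifit3 and Irf7 in TPM for each library, with grey for the control ASO, orange for the Hnrnph2 ASO, filled points for WT and open points for mutants; bars give the mean and SD. The spread was widest in P209L mice with the Hnrnph2 ASO at 3 weeks (n = 2), where Isg15 stood at 25.8 ± 27 TPM.

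Some microglial and activity genes were higher in the average over mutants with the ASO, although none of these lists passed with the estimated correlation. The lists carry names of cell types, but the RNA was not separated by cell type. Whether the activated microglia and reactive astrocyte calls are separate from the rise of the interferon genes was not tested. Of 18 homeostatic microglia genes, 4 were called higher, the complement genes C1qa (0.47), C1qb (0.46) and C1qc (0.44) and the receptor gene Trem2 (0.38), and 6 adjusted over the list alone (median 0.16, and 0.093 without P209L Hnrnph2 ASO replicate 1 at 3 weeks, adjusted p with the estimated correlation 0.362). Of 19 activated microglia genes, 4 were called higher, Cd68 (0.43), Lyz2, H2-K1 (0.40) and B2m (0.34), and 7 adjusted over the list alone (median 0.15, adjusted p with the estimated correlation 0.361), with 2 without Hnrnph2 ASO replicate 2 of the P209L cohort at 3 weeks and 7 without R206W control replicate 3. Of 30 immediate early genes, 5 were called higher, among them Fosb (0.72), Egr4 (0.61), Apold1 (0.53) and Sik1 (0.39), and 19 adjusted over the list alone (median 0.37, adjusted p with the estimated correlation 0.361). Their medians by cohort were 0.767 in P209L at 8 weeks, -0.0145 in P209L at 3 weeks (n = 2 with the Hnrnph2 ASO) and 0.238 in R206W, so the P209L cohort at 3 weeks had no such rise. The count of 5 fell to between 1 and 3 without any 1 of 14 of the 17 libraries, as to 1 without P209L control replicate 1 at 8 weeks, and was 8 without R206W control replicate 3. Among 20 reactive astrocyte genes, C4b (0.67) and Iigp1 (0.51) were called higher, with 4 adjusted over the list alone (median 0.16, and 0.263 without P209L Hnrnph2 ASO replicate 1 at 3 weeks, adjusted p with the estimated correlation 0.57). Without Hnrnph2 ASO replicate 2 of the P209L cohort at 3 weeks limma called 0 of them (6 at an unadjusted p under 0.05), and without R206W control replicate 3 it called 4. Gabra3 (-0.35) and Gabbr1 (-0.25) were called lower among 19 genes of GABA receptors and the inhibitory synapse, with 4 lower adjusted over the list alone (median -0.06, from -0.0906 without P209L Hnrnph2 ASO replicate 3 at 8 weeks to -0.0349 without R206W control replicate 1, and -0.0362 without P209L Hnrnph2 ASO replicate 2 at 8 weeks, adjusted p with the estimated correlation 0.624). Of 39 postsynaptic density genes, Shank1 and Dlg4 (-0.18) were lower and Dlgap3 (0.19) was higher, with 3 lower and 1 higher adjusted over the list alone (median -0.05, adjusted p with the estimated correlation 0.888). Camera with the preset correlation passed 12 of 47 lists upward and 5 downward, and 0 passed with the estimated correlation.

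Whether mutants with the Hnrnph2 ASO still differed from WT with the control ASO was asked next. Hnrnph2 remained lower, by -3.49 in P209L mice at 8 weeks, by -2.89 at 3 weeks and by -2.22 in R206W mice. At 8 weeks it was the only gene called, and Rufy1 (-0.60), Hist2h2aa1 (1.38) and Col11a2 (0.61) did not pass (adjusted p 0.182). The count was 4 and 2 without P209L Hnrnph2 ASO replicates 2 and 3, and stayed 1 with the replicate number as a block. In the P209L cohort at 3 weeks the other called gene was Crybb1 (0.80, adjusted p 0.00803), whose call ended without P209L Hnrnph2 ASO replicate 2 (adjusted p 0.0517). There the count of 2 was 115, 8 and 5 without P209L Hnrnph2 ASO replicate 1, P209L Hnrnph2 ASO replicate 2 and WT control replicate 3. In the R206W cohort the other called genes were the unnamed models Gm29514 (-0.80) and Gm45716 (0.91), named after their values were seen, with 5 genes without WT control replicate 1 and 1 without R206W Hnrnph2 ASO replicate 2. The deviations of same-numbered libraries correlated there, and with the number as a block limma called 236 genes, 56 higher and 180 lower. WT with the control ASO and R206W with the Hnrnph2 ASO share no name stem, so what remained cannot be separated from the stem. Rescaled values gave 4 genes in the R206W cohort, 3 higher and 1 lower. Unadjusted p-values under 0.05 numbered 966, 1975 and 2074 in the 3 cohorts, so smaller differences were not ruled out. For the mutation effect itself they numbered 1038, 1463 and 1469, fewer than for the remaining difference in both cohorts at 3 weeks. The few calls therefore do not show a return to WT across all genes.

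The difference between the ASO effects in mutants and in WT was tested as an interaction. Averaged over the cohorts, limma called 50 genes, 47 more strongly lowered in mutants and 3 raised. Ddn (-1.05, SE 0.11, adjusted p 5.01e-07), Ppp1r9b (-1.02, SE 0.073, adjusted p 1.84e-09), Shank1 (-0.80, SE 0.079, adjusted p 4.77e-07), Ilrun (-0.80, SE 0.062, adjusted p 7.03e-09) and Tnpo2 (-0.70, SE 0.066, adjusted p 2.56e-07) led the lowered genes, followed by Adra1b, Dzip1, Ppm1a, Stac2 and Marf1 at -0.68 to -0.54. Bfsp2 (0.58, SE 0.13, adjusted p 0.0493), Dnal4 (0.34, SE 0.068, adjusted p 0.0155) and Tceal5 (0.22, SE 0.045, adjusted p 0.0213) were raised. The call of Bfsp2 ended without any 1 of 25 of the 35 libraries (adjusted p 0.0512 to 0.13), and that of Tceal5 without Hnrnph2 ASO replicate 2 of the P209L cohort at 3 weeks (adjusted p 0.0503). All 47 lowered genes were among the 422 higher in mutants, where 1.2 would be if the calls were independent, but both contrasts use the mutant controls. Of 22 interferon genes limma called 0 for the interaction (8 at an unadjusted p under 0.05), with 0 adjusted over the list alone, a median of 0.37 and an adjusted p with the estimated correlation of 0.9.

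To compare mutation and ASO effects without shared libraries, the mutation effect of a cohort was set against the ASO effect in mutants of another. Of 143 such calls of mutation genes, 135 had the opposite sign. Each call was read in both other cohorts, so the same genes recur among the 143. Across all genes, which are not independent replicates, the mean r was -0.111. Over the 6 pairs r ran from -0.299 to 0.0392, the last for the R206W mutation against the ASO in P209L at 3 weeks. Against the ASO effect in WT of another cohort, 77 of these calls had the opposite and 66 the same sign (mean r 0.0687). Within a cohort, where both effects use the mutant controls, r was -0.491, -0.268 and -0.356, beside -0.488, -0.456 and -0.509 in simulations with no effect. The covariances were -0.0182, -0.0124 and -0.0126, beside -0.0172, -0.018 and -0.0163 simulated. Of the genes called for the mutation, 72 of 72 had opposite signs within cohorts, a count that sharing controls also favours.

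Age was compared in WT with the control ASO (8 against 3 weeks, n = 3 each, both of the same library series), as the setting of the P209L effects. Each age was a separate cohort and the groups shared no animal-name stem, so age cannot be separated from cohort or stem. Genes of developing oligodendrocytes fell. Gpr17, a receptor of differentiating precursors, went from 76.9 ± 6.12 TPM at 3 weeks to 23.9 ± 2.62 at 8 weeks (SD; log2 fold change -1.65, adjusted p 1.28e-08), Enpp6, of newly forming oligodendrocytes, changed by -1.42 and Ugt8a, an enzyme of myelin lipid synthesis, by -1.56. Eln, the elastin gene, changed by -1.59, Rab7b by -1.54, Marcksl1 by -1.45, Il23a by -1.45, Hist2h2aa1 by -1.44 and Kif19a and Gsn by -1.35 each. Il33, an alarmin of glia, went from 8.48 ± 1.4 to 42.9 ± 7.3 TPM (2.21, adjusted p 1.24e-10). Serpinb1a rose by 1.97, the noncoding RNAs Rn7sk, Neat1 and Snord17 by 1.96, 1.73 and 1.36, Adamtsl4 by 1.25, Qdpr by 1.18, Xdh by 1.04, Lyz2 by 0.99 and Hsf4 by 0.94. Hnrnph1 rose by 0.37 (adjusted p 0.000285) and Hnrnph3 by 0.49 (adjusted p 0.0036). limma called 1891 genes, 457 higher and 1434 lower, against 1733 genes, 736 higher and 997 lower, with rescaled values. The count was 998 and 2963 without WT control replicates 2 and 3 at 8 weeks, and 1040 and 1081 without WT control replicates 1 and 3 at 3 weeks. The call of Rn7sk ended without replicate 2 at 8 weeks or 2 or 3 at 3 weeks (adjusted p 0.0576 to 0.199), that of Snord17 without replicate 2 or 3 at 8 weeks or 3 at 3 weeks (0.0885 to 0.189) and that of Lyz2 without replicate 2 at 8 weeks or 1 at 3 weeks (0.051 and 0.055).

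Of 15 genes of oligodendrocyte precursors, 11 were called lower at 8 weeks and 13 adjusted over the list alone (median -0.59), the 1 list of 47 that passed with the estimated correlation (adjusted p 0.0338). Of 21 myelinating genes, 13 were called lower, among them Cldn11 (-1.23), Mog (-1.16) and Cnp (-1.04), and 1 higher, with 15 lower and 1 higher adjusted over the list alone (adjusted p with the estimated correlation 0.229). Of 23 cholesterol synthesis genes, 15 were called lower, among them Hmgcs1 (-0.77), Cyp51 (-0.69) and Fdps (-0.55), with 18 adjusted over the list alone (adjusted p with the estimated correlation 0.5). Of 25 genes of immature neurons and axon growth, 16 were called lower, among them Sox4 (-0.75), Dpysl5 (-0.66) and Crmp1 (-0.44), with 20 adjusted over the list alone (adjusted p with the estimated correlation 0.229). Of 73 cytosolic ribosomal protein genes, 19 were called higher, Rpl30 (0.44) and Rps23 (0.41) among them, and 1 lower, with 31 higher and 1 lower adjusted over the list alone (adjusted p with the estimated correlation 0.712).

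Whether the P209L effect differed between ages, the ASO effect in WT between ages, or the P209L from the R206W effect at 3 weeks was tested for every gene. limma called 0 genes in each of these 3 differences, with 515, 427 and 392 at an unadjusted p under 0.05. The smallest p-values belonged to Shtn1 (-0.38), Gna15 (0.84, adjusted p 0.635) and mt-Co3 (1.78, adjusted p 0.88) for P209L between ages, to Ndufa4l2 (0.62), Ten1 (-0.46) and Rps12l1 (-2.07, adjusted p 0.999) for the ASO between ages, and to Plac9a (-1.68) and Ap4m1 among others for P209L against R206W, and none passed. Without WT Hnrnph2 ASO replicate 1 at 8 weeks, 2 genes were called for the ASO between ages, and without WT control replicate 2 of the P209L cohort at 3 weeks, 1 for P209L against R206W.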

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

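The tests on reads shared by the paralogs, on blood, on a single cohort and on splits that part pairs were chosen after their values had been seen, and the other tests of explanations after the pattern they address but before their own values.

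The ASO effect differed between mutants and WT for 50 genes of the average interaction, which is what drew attention to them. Ddn (-1.05), Ppp1r9b (-1.02), Shank1 (-0.80), Ilrun (-0.80), Tnpo2 (-0.70), Adra1b (-0.68), Dzip1 (-0.60), Ppm1a (-0.58), Stac2 (-0.54) and Marf1 (-0.54) fell more in mutants, and Bfsp2 (0.58), Dnal4 (0.34) and Tceal5 (0.22) rose more. Other splits of the same libraries gave as many genes in 1 of 100, the real split included, and at most 13 otherwise. These splits exchanged ASO labels within each genotype. They also broke any ASO effect common to both genotypes, so they cannot test the interaction alone. For the target and its paralog, 24 differences were tested with limma and adjusted together, and 7 passed. At 8 weeks Hnrnph2 fell more in P209L than in WT mice (-0.84, adjusted p 0.00364), and at 3 weeks Hnrnph1 rose less in P209L than in WT mice (-0.38, adjusted p 0.00364). In WT the fall of Hnrnph2 was larger at 8 weeks than in the R206W cohort (-0.57, adjusted p 0.0452). In mutants it was larger at 8 weeks than in P209L at 3 weeks (-0.63, adjusted p 0.0405) and than in R206W (-1.21, adjusted p 0.000155). The rise of Hnrnph1 in WT of the P209L cohort at 3 weeks was larger than in WT at 8 weeks (8 minus 3 weeks -0.29, adjusted p 0.0155) and than in WT of the R206W cohort (0.40, adjusted p 0.00189). Age, substitution and litter stay open as untested explanations for these differences.

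Hnrnph1 was higher with the Hnrnph2 ASO in every cohort and genotype. Reads of one paralog assigned to the other may raise Hnrnph1 as Hnrnph2 falls. In WT of the P209L cohort at 3 weeks the sum of both genes rose by 52.2 TPM (SE 14.7). TPM divides reads by transcript length, so moved reads need not keep this sum, and its rise cannot decide the question. In the other 5 comparisons the sum rose by at most 3.84 TPM (SE 18.2, in WT at 8 weeks). It changed by -11.1 in P209L at 8 weeks (SE 14.3), by -28.8 in P209L at 3 weeks (SE 3.34) and by -11.7 and -13.1 in WT and mutants of the R206W cohort (SE 23.1 and 20.1). Shared reads and a rise of Hnrnph1 itself therefore cannot be told apart. Reads moved from Hnrnph2 to Hnrnph1 would also enlarge the measured fall of Hnrnph2. A difference in the scale of whole libraries is argued against by the rise of 0.403 with rescaled values in WT. A response of Hnrnph1 to the loss of Hnrnph2, which the ASO groups would allow, stays open as a hypothesis.

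Type I interferon genes had a higher median in mutants with the Hnrnph2 ASO (log2 fold change 0.55), although the list did not pass with the estimated correlation (adjusted p 0.361). A single mutant library is argued against as the whole cause, since the lowest median without 1 library was 0.335 (without Hnrnph2 ASO replicate 2 of the P209L cohort at 3 weeks), although limma then called 0 of the 22 genes, with 14 at an unadjusted p under 0.05. A single cohort is argued against too, with a lowest median of 0.478. For the mutation itself the list medians were -0.0476 in P209L at 8 weeks, 0.178 in P209L at 3 weeks and 0.472 in R206W. R206W control replicate 3, at a mean of 3.764 on the log2 scale, lay above the R206W libraries with the Hnrnph2 ASO (3.373 to 3.678). Interferon genes thus also varied between mutant libraries without the Hnrnph2 ASO. Blood left in the tissue may contribute and cannot be told apart. The 8 erythrocyte genes had a median of 0.0619 (SE over genes 0.029), while the 6 peripheral leukocyte genes had 0.226 (SE over genes 0.073). These medians moved with single libraries. The erythrocyte median ran from -0.0077 without R206W Hnrnph2 ASO replicate 3 to 0.189 without P209L Hnrnph2 ASO replicate 2 at 3 weeks. It was 0.0978, 0.0141 and 0.0964 without P209L control replicates 1, 2 and 3 at 8 weeks, and 0.0253 and -0.00307 without P209L control replicate 2 and Hnrnph2 ASO replicate 1 at 3 weeks. In the R206W cohort it was 0.00757 and 0.121 without mutant control replicates 1 and 3, and 0.152 without mutant Hnrnph2 ASO replicate 2. The leukocyte median was 0.138 without R206W Hnrnph2 ASO replicate 1 and at most 0.326, without P209L Hnrnph2 ASO replicate 1 at 3 weeks. In the R206W cohort, with 2 name stems of the animals for each ASO and none shared, a difference between stems cannot be told apart from the ASO. An effect of the ASO in mutants stays open, and 0 of the 22 genes passed limma for the interaction, with 8 at an unadjusted p under 0.05.

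Genes of myelin, of vessels and of early neuronal activity had lower list medians in the average over the mutants. A different share of cerebellum in the libraries may give such a pattern, but with the cerebellar markers as a covariate the highest of the 4 list medians was -0.14. With rescaled values it was -0.167, which argues against the scale of the libraries. A single cohort is argued against for myelin and leptomeningeal genes, whose highest median without 1 cohort was -0.151. For the other lists it cannot be told apart. Pericyte genes were at -0.0901 without P209L at 3 weeks (SE over genes 0.034). Immediate early genes were at -0.116 without P209L at 8 weeks (SE over genes 0.0281) against -0.448 without R206W. In R206W alone their median was 0.0912. A different amount of blood stays open, since erythrocyte and peripheral leukocyte genes were lower too (medians -0.339 and -0.273), although in R206W the erythrocyte median was 0.00585 beside -0.335 for leptomeningeal genes. Other differences in dissection were not tested, since the labels name both whole brain and cortex. An effect of the substitutions on these cells stays open as a hypothesis, with an adjusted p of 0.459 at the smallest when the correlation within lists was estimated.

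For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. The real mutation effects called 28 genes in P209L at 8 weeks, 22 in P209L at 3 weeks and 22 in R206W, and the highest other splits gave 1, 1 and 2. The real ASO effects in WT called 3, 2 and 2 genes, and the highest others gave 1, 3 and 3. The real ASO effects in mutants called 15 at 8 weeks and 16 in R206W, and the highest others gave 1 and 2. The real remaining differences called 1 at 8 weeks and 3 in R206W, and the highest others gave 1 and 1. The real split of these called 1 and 236 genes with the replicate number as a block. The other splits that part all 3 same-numbered pairs gave at most 1 in either cohort. Age called 1891 genes and the highest other split 1267. Among 100 splits of the averages, only the real one reached its count for the mutation (708 genes, highest other 164). That highest other split exchanges WT control replicate 1 and R206W control replicate 1 of the R206W cohort. For the ASO in mutants, too, only the real split reached its count (414, highest other 24). A share of 1 in 100 is the smallest that these splits can give. Chance is thus made less likely for these averages but is not excluded. For the ASO in WT 2 of the 100 splits, the real one included, gave 31 genes or more. The other gave 1108, which points to a structure of the samples unrelated to the ASO. The splits therefore cannot set the 31 genes apart from such a structure. For the 3 differences between cohorts the real count was 0, which all 100 splits reach whatever the data, so the splits say nothing about chance there. Their highest others were 4, 1054 and 31, and a split with 1054 points to a structure of the samples.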

How the results depend on the processing

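Each alternative changed 1 choice at a time. Chosen after the data were seen were the cerebellar covariate, leaving out single libraries for the averages, the age effect and the differences between cohorts (WT Hnrnph2 ASO replicate 3 of the P209L cohort at 3 weeks, the library furthest from its group, among them), and the alternatives for the list tests and for the correlations between cohorts. Of the values that answer a comparison, 822 kept their direction and side of the threshold or their size, 111 moved, 2 became stronger, 2 became weaker and 0 changed sign. Of the values for single genes and lists, 9231 kept theirs, 736 moved, 571 lost and 79 gained a call, and 13 changed sign with a call of the gene or list in at least 1 of the fits compared. Among those that kept theirs, sign changes with a call in neither fit numbered 77 for list medians and 90 for genes with 1 library left out, and 47 and 19 with other alternatives. The cause was not tested unless one is named.

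With no filter on low values, the mutation effect in P209L at 8 weeks called 18 genes, the ASO in WT 1 and the remaining difference from WT 5. In the P209L cohort at 3 weeks the ASO in WT called 4 genes, the ASO in mutants 30 and the remaining difference 13, and in the R206W cohort the remaining difference called 1. The differences between cohorts called 1 gene (P209L between ages), 2 (ASO in WT between ages) and 2 (P209L against R206W), and the mean correlation of the mutation effects across genes was 0.205. With a pseudocount of 0.1 TPM the mean correlations between cohorts were 0.143 for the mutation, 0.0815 for the ASO in WT and 0.126 for the ASO in mutants. A smaller pseudocount gives more weight to genes of low level by its construction. With median-of-ratios rescaling the ASO in P209L mice at 8 weeks called 28 genes.

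With only the compared groups in the fit, fewer libraries estimate the spread. The mutation effect then called 2 genes in P209L at 8 weeks and 2 in R206W, and the ASO in WT at 8 weeks called 6. The remaining difference called 3 genes in P209L at 8 weeks, 9 in P209L at 3 weeks and 15 in R206W, and the mean correlation of the mutation effects was 0.303. Hnrnph1 in WT of the P209L cohort at 3 weeks no longer passed (log2 fold change 0.656, adjusted p 0.0603), nor with ratios to reference genes (0.549, adjusted p 0.166). With a joint fit of all 35 libraries, more libraries estimate the spread. At 8 weeks 77 genes were then called for the mutation, 93 for the ASO in mutants and 22 for the remaining difference, and Hnrnph1 passed for the ASO in WT (0.362, adjusted p 0.0474) and in mutants (0.304, adjusted p 0.0189). In the P209L cohort at 3 weeks 105 genes were called for the mutation, 4 for the ASO in WT, 41 for the ASO in mutants and 181 for the remaining difference, and in the R206W cohort 48 for the mutation, 40 for the ASO in mutants and 79 for the remaining difference.

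With the replicate number as a block, the mutation effect called 16 genes in P209L at 8 weeks and 210 in R206W. These 210 were 102 higher and 108 lower, beside 21 and 1 without the block. The ASO in WT called 1 at 8 weeks and the ASO in R206W mice 67. The remaining difference called 1 gene in P209L at 3 weeks and 236 in R206W, the average ASO effect in WT 53 and the age effect 930. The median of the interferon list for age changed sign, to 0.195. Across genes, deviations of libraries sharing a number correlated between -0.197 and 0.24 in the P209L cohort at 8 weeks (7 of 18 pairs over 0.1). They correlated between -0.164 and 0.109 in the P209L cohort at 3 weeks (1 of 15) and between 0.00289 and 0.204 in the R206W cohort (9 of 18). All R206W values lay above 0, so pairs cannot be told apart there from a difference by number across the whole cohort. For the remaining difference from WT at 8 weeks and in R206W every pair lay over 0.1. Giving the block beside those results was a choice made from the data. With the animal-name stem as a block the mutation effect in R206W called 19 genes, and the calls of Adra1b (0.85, adjusted p 0.0931) and Cbln3 (-0.78, adjusted p 0.196) ended. With robust eBayes none of the counts of called genes moved by over 1.5 times.

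Without the P209L cohort at 8 weeks, the P209L cohort at 3 weeks or the R206W cohort, fewer libraries remain. The average mutation effect then called 331, 210 and 218 genes, the ASO in WT 12, 18 and 5, the ASO in mutants 140, 171 and 138 and the interaction 17, 22 and 26. Without the R206W cohort 7 lists passed camera for the ASO in WT. For the ASO in WT the medians of the striatum list (0.0132), the immature neuron list (0.0451) and the stress response list (0.0275) then changed sign, as did those of the immature neuron list for the ASO in mutants (0.0726) and of the cell cycle list for the interaction (-0.00686). With the cerebellar covariate the median of the cerebellar list for the mutation changed sign, to 0.00445, since the covariate is the mean of that list.

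Leaving out single libraries changed the sign of 6 medians of lists that passed camera with or without the library. These were the nuclear oxidative phosphorylation list for the mutation (-0.016) and for age (0.0189), both without WT control replicate 3 at 8 weeks, and the GABA receptor list for the ASO in WT without that library (0.0225) or WT Hnrnph2 ASO replicate 1 at 8 weeks (0.011). The others were, for the interaction, the oligodendrocyte precursor list without P209L Hnrnph2 ASO replicate 1 at 3 weeks (-0.00634) and the ribosomal list without WT control replicate 2 at 8 weeks (-0.00197). With each library left out in turn, the oxidative phosphorylation list ran from -0.016 to 0.0245 for the mutation and from -0.106 to 0.0189 for age, and the GABA receptor list from -0.0896 to 0.0225. For the interaction the precursor list ran from -0.00634 to 0.105 and the ribosomal list from -0.00197 to 0.0645. Counts of called genes with 1 library left out ran, in P209L at 8 weeks, from 5 to 84 for the mutation, 1 to 2 for the ASO in WT, 8 to 12 for the ASO in mutants and 1 to 4 for the remaining difference. They ran in P209L at 3 weeks from 11 to 14, 2 to 7, 11 to 47 and 3 to 115, and in R206W from 10 to 25, 1 to 4, 9 to 43 and 1 to 5. Where an arm then held 1 library, it was assumed to vary like the other groups. For the averages they ran from 482 to 1164 for the mutation, 21 to 40 for the ASO in WT, 73 to 263 higher and 136 to 298 lower for the ASO in mutants and 40 to 74 for the interaction, and for age from 998 to 2963. The differences between cohorts gave 0 to 0, 0 to 2 and 0 to 1, in the order above. Lists passing camera ran from 14 to 22 for the mutation, 7 to 15 for the ASO in WT, 14 to 20 for the ASO in mutants, 7 to 17 for the interaction and 12 to 21 for age.

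Hnrnph2 kept its fall with every library left out, from -2.72 to -2.36 in WT at 8 weeks, -2.59 to -2.48 in WT of the P209L cohort at 3 weeks, -2.06 to -1.91 in WT of the R206W cohort and -2.42 to -2.30 on average. In mutants it ran from -3.63 to -3.30, -2.89 to -2.67, -2.29 to -2.15 and -2.87 to -2.76. Hnrnph1 ran in WT from 0.314 to 0.409, 0.621 to 0.703, 0.197 to 0.301 and on average 0.405 to 0.441, and in mutants from 0.26 to 0.351, 0.261 to 0.295, 0.217 to 0.317 and 0.267 to 0.301. Mean correlations between cohorts ran from 0.202 to 0.268 for the mutation, 0.101 to 0.161 for the ASO in WT, 0.124 to 0.231 for the ASO in mutants and -0.122 to -0.0916 for mutation against ASO in mutants. The read depth is unknown, so which changes depth limits could not be read from the files.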

Other observations

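The genes and values of this part were chosen after the results were seen, and the tests below were not planned. Rufy1, an adaptor of early endosomes that lies next to Hnrnph1 on chromosome 11, was lower with the Hnrnph2 ASO in both genotypes. In WT it went from 21.6 ± 0.816 to 15.7 ± 1.73 TPM (SD, n = 3) at 8 weeks, from 20.4 ± 1.42 to 14.3 ± 1.14 in the P209L cohort at 3 weeks and from 20.1 ± 0.772 to 14.8 ± 0.746 in the R206W cohort. In mutants it went from 22.2 ± 1.27 to 14 ± 1.51, from 20.5 ± 0.559 to 13.4 ± 1.28 (n = 2) and from 21.2 ± 2.3 to 14.3 ± 0.868. For the substitutions themselves Rufy1 changed by 0.04 on the log2 scale (adjusted p 0.737). Whether the ASO acts on this transcript directly was not analysed here, since its sequence was not at hand.

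Some genes with roles in neurons and glia moved in opposite directions with the substitutions and with the ASO in mutants. The neuronal RNA-binding protein gene Elavl3 was higher by 0.21 in mutants (SE 0.028) and changed by -0.24 with the ASO (SE 0.029). The disease gene Med13l was higher by 0.45 (SE 0.081) and changed by -0.42 (SE 0.084). Slc32a1, the vesicular transporter of inhibitory transmitters, was higher by 0.25 and changed by -0.21. Gla, a lysosomal enzyme gene beside Hnrnph2 on the X chromosome, was lower in mutants (-0.26, SE 0.049) and rose by 0.27 with the ASO (SE 0.051). Glul, the glutamine synthetase gene of astrocytes, changed by -0.26 and rose by 0.34. In WT the ASO called none of these genes in limma, with adjusted p of 0.452 for Elavl3, 0.988 for Med13l, 0.667 for Slc32a1, 0.519 for Gla and 0.452 for Glul. Both effects use the mutant controls, which favours opposite signs.

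WT mice with the control ASO at 3 weeks differed between the library series of the R206W and the P209L cohorts. limma called 899 of 16556 genes, 607 higher and 292 lower in the R206W cohort. The cerebellar gene Gabra6 was higher by 0.85 (adjusted p 0.0244), Hnrnph1 by 0.46 (adjusted p 0.000817) and Hnrnph3 by 0.42 (adjusted p 0.0301). These are mice of the same age, genotype and ASO, so the change of Hnrnph1 and Hnrnph3 with age is of a size also seen between series.

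The main axis of the differences within groups held 14.4% of them. WT control replicates 2 and 3 at 8 weeks had the weights furthest apart, 0.463 and -0.364. A score over 147 age genes, chosen in other libraries of the P209L cohorts, was read in the 18 libraries not used to choose them. It lay between 0.582 and 0.692 in the 3 of them at 8 weeks and between -0.469 and -0.127 in those at 3 weeks, so none of the 18 stood on the other side of its labelled age. Across genes, which are not independent replicates, the axis correlated with the mutation effects at -0.136, -0.000444 and -0.0265 in the P209L cohort at 8 weeks, the P209L cohort at 3 weeks and the R206W cohort. Its largest correlations were with the ASO effects at 8 weeks, 0.211 in mutants and -0.145 in WT. The libraries furthest from their group means were WT Hnrnph2 ASO replicate 3 of the P209L cohort at 3 weeks (root mean square 0.335) and WT control replicates 2 and 3 at 8 weeks (0.313 and 0.299).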
